A study of Rattus norvegicus with 8 samples.

How the data were processed

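Total RNA from the habenula of 8 male Sprague-Dawley rats was profiled on an Affymetrix whole-transcript microarray with biotin-labelled target. The stressed group held 4 rats that were restrained in breathable plastic film for 2 hours a day over 14 days, and the non-stress group held 4 rats left in the home cage. Each array was a separate rat, the rat numbers are not shared between the groups, and so the arrays were compared unpaired. No scan dates or hybridization batches were given in the sources used here, so a batch effect could not be checked.

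The deposited expression values are log2 intensities per probe set. The authors' background correction, summarization, normalization and scanner, and the number of probe sets on the array, are not given in the sources used here. The 2 deposited tables held the same 379 probe sets with the same values (largest gap 0). The authors' deposited table also holds a column named as a fold change, which equals the log2 difference of the group means, stress minus non-stress, to within 3.83e-15. The deposited p-value of each probe set equals a 2-sided unequal-variance p computed from the 8 values, to within 1.64e-15, and is not adjusted for the number of tests.

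In the authors' deposited table the largest p-value was 0.0499 and the smallest absolute log2 difference was 0.26, a fold of 1.20. The 379 probe sets are therefore a list chosen on these same 8 arrays by a p-value and a fold rule. This choice bears on every number in the results. Sizes of differences are inflated by the choice, the count of probe sets past a threshold describes the list and is not a test over the genome, and a gene missing from the table was either not past both rules or not measured. No enrichment against other genes was run.

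Gene symbols came from the platform's probe annotation and were matched by gene ID to the RefSeq gene table for the rat. Of the 379 probe sets, 283 (74.7%) had 1 symbol, 5 had several and 91 had none. Probe sets with several symbols or none were kept in counts and were not named. Genomic coordinates are not given, because no genome build was named in the sources used here.

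Stress and non-stress were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, no covariates), with Benjamini-Hochberg adjustment over the 379 probe sets and a threshold of 0.05. Each difference is given as log2 stress minus non-stress with limma's standard error, and levels are means ± SD over 4 rats. The limma fit was tested on simulated data of 379 probe sets with the spread of the real ones. It recovered 45 of 67 changes of 1.2-fold (67.2%), 67 of 67 of 1.5-fold and 66 of 66 of 2-fold, and called 3 of 179 unchanged probe sets. The choice of the table was also simulated. Of 20000 unchanged probe sets, 136 passed both rules. All 136 then passed limma when adjusted among themselves, and 60.3% had groups that did not overlap. Their spread was drawn from the 379 probe sets, which had been kept for small p-values. The counts therefore need not hold for the whole array.

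Before the data were examined, 29 gene lists were fixed for this tissue and treatment, with markers of the cell types and neighbouring structures that a habenula dissection can hold among them. Olfactory receptor genes were matched by their current or earlier symbols. The lists covered medial and lateral habenula neurons, thalamic neurons, hippocampal and dentate neurons, choroid plexus, ependyma and subcommissural organ, pineal gland, oligodendrocytes and their precursors, astrocytes, microglia, endothelial and mural cells, meninges and fibroblasts, blood cells, immediate early genes, glucocorticoid responsive genes, circadian clock genes, cholinergic, glutamatergic and GABAergic synapse genes, monoamine genes, neuropeptides and their receptors, voltage-gated and potassium channels, cAMP signalling, heat shock and chaperone genes, oxidative phosphorylation, ribosomal proteins, chemosensory receptors and small non-coding RNAs. For each list with at least 3 members in the table, a score per rat was the mean over members of the log2 value minus the gene's mean over the 8 arrays. The scores were compared with a 2-sided exact permutation test over the 70 orders of the arrays, for which the smallest possible p is 0.0286, and adjusted over the 11 lists tested. Since list members had been chosen on the same arrays, this test could hardly fail for a list whose members go 1 way, and its p-values are treated as void. After the table was found to be a chosen list, Fisher's exact test of direction was added, which asks whether a list's members were higher or lower more often than the other probe sets of the table. Pearson and Spearman correlations of the hippocampal and medial habenula scores, on residuals from the group means with exact permutation of rats within groups, were also added after the values were seen.

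The genes named are the 12 largest differences in each direction among annotated probe sets whose groups did not overlap, and up to 4 members of each list by size of difference, 63 genes in all. Any other gene is said to have been chosen after its values were seen. Alternatives were an equal-variance test, limma with an intensity trend or array weights, median-centred or quantile-normalized arrays, a filter on the dimmest 25% of probe sets, named genes alone, the other deposited table, looser thresholds, scores from medians or from genes scaled by their SD, and leaving out each rat in turn. Adjustment of the deposited and of limma's p-values for an assumed number of probe sets tested, and scores of the clock and glucocorticoid lists without the gene they share and of the medial habenula list without cholinergic genes, were added after the data were seen. Scores, permutations and plots were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Precision is limited by the 4 arrays per group.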

Results

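Habenula gene expression was measured in 4 rats after 14 days of daily restraint and in 4 rats kept without stress, with 1 array per rat. The values cover 379 probe sets that had been chosen on these same arrays for a difference between the groups, 283 of them with a single gene symbol. Array medians lay between 8.60 and 8.77 on the log2 scale. The root mean square difference between arrays was 0.146 to 0.270 within groups and 0.321 to 0.539 between groups. Values below are log2 means ± SD with n = 4 rats in each group, and differences are stress minus non-stress with limma's standard error.

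The comparison asks which transcripts of the habenula differ after chronic restraint. The largest difference was in Zbtb16, a transcriptional repressor that glucocorticoids induce in many tissues, which was 3.91-fold higher in the stressed rats (9.78 ± 0.21 against 7.81 ± 0.09, difference 1.97 ± 0.10, adjusted p = 1.60e-10). That p-value is limma's, with spread and adjustment taken over the chosen probe sets alone. The authors' unadjusted unequal-variance p for Zbtb16 was 7.44e-05. Pdk4, a kinase that restrains pyruvate oxidation, was 2.27-fold higher, and Sgk1, a serum and glucocorticoid regulated kinase, was 2.13-fold higher. Gpd1, the cytosolic glycerol-3-phosphate dehydrogenase, was 2.07-fold higher. The largest difference in the other direction was in Gpr149, an orphan receptor, with non-stress rats 1.73-fold above stressed rats (9.43 ± 0.34 against 8.65 ± 0.12, difference -0.79 ± 0.13). Chrnb4, a nicotinic receptor subunit gene, and Slc18a3 and Slc5a7, the transporter genes for acetylcholine and choline, were also lower.

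Of the 379 probe sets, 169 were higher and 210 lower in the stressed rats, so that 44.6% were higher. All 379 passed limma's threshold, with adjusted p-values from 1.60e-10 to 0.0121, as a table chosen for small p-values must nearly do. The differences were mostly small, with a median of 0.32 among the higher and -0.34 among the lower probe sets. Only 31 exceeded 1.5-fold, 23 of them higher, and 4 exceeded 2-fold, all of them higher. The groups did not overlap in 316 probe sets (83.4%); of simulated unchanged probe sets that pass the same p-value and fold rules, 60.3% did not overlap either. When the authors' deposited p-values were adjusted for an assumed 20000 tests, 1 probe set passed, without a gene symbol (6.87 ± 0.02 in stressed and 6.28 ± 0.03 in non-stress rats). With limma's p-values 48 passed, Zbtb16, Gpd1, Hif3a and Lims2 among them, but limma estimates the spread on the chosen probe sets. Of the 136 chosen among 20000 simulated unchanged probe sets, 18 passed in the same way. Their smallest unadjusted limma p was 2.95e-14, below the 4.23e-13 of Zbtb16, the smallest of the real probe sets. The simulated spread was also that of the chosen probe sets, so 18 does not measure false calls among the 48.

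Differences of list scores are given below as sizes. The exact permutation test fixed for them gave the smallest p that 4 against 4 rats allow for 7 of the 11 lists with at least 3 members (adjusted p = 0.0449) and adjusted p-values of 0.0786 to 0.114 for the other 4. Because the members had been chosen for a difference between these same arrays, that outcome was set largely by the choice, and the test is void as evidence that a list changed. The direction of a probe set was not part of the choice, so Fisher's exact test of direction against the rest of the table is given for each list, although genes that vary together are not independent in it.

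Glucocorticoid responsive genes had the largest score difference of the 11 lists tested. This list held 25 symbols, alternative names of the same gene among them. In the table were 15 of its genes, 14 higher and 1 lower in the stressed rats. Besides Zbtb16, Pdk4 (9.85 ± 0.54 against 8.67 ± 0.09, difference 1.18 ± 0.18) and Sgk1 (11.98 ± 0.41 against 10.89 ± 0.23, difference 1.09 ± 0.16), the sulfotransferase Sult1a1 was higher by 0.77 ± 0.11 and the NF-kappa-B inhibitor Nfkbia by 0.72 ± 0.10. Fkbp5, a co-chaperone of the glucocorticoid receptor (0.60 ± 0.10), Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein (0.46 ± 0.08), and Klf9 (0.44 ± 0.08) were also higher, and these 3 were chosen after their values were seen. The exception, likewise chosen afterwards, was the kinase Map3k6 at -0.38 ± 0.10. All 15 passed over the whole table and all 15 adjusted over the list alone, but the table was chosen on these samples, so neither count is independent evidence. The list score differed by 0.67 between the groups. Its members were higher more often than the rest of the table (Fisher's exact test, adjusted p = 0.000449). Stressed rat 8 had a score of 0.07, against 0.38 to 0.49 in the other 3 stressed rats.

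**Figure D1:**
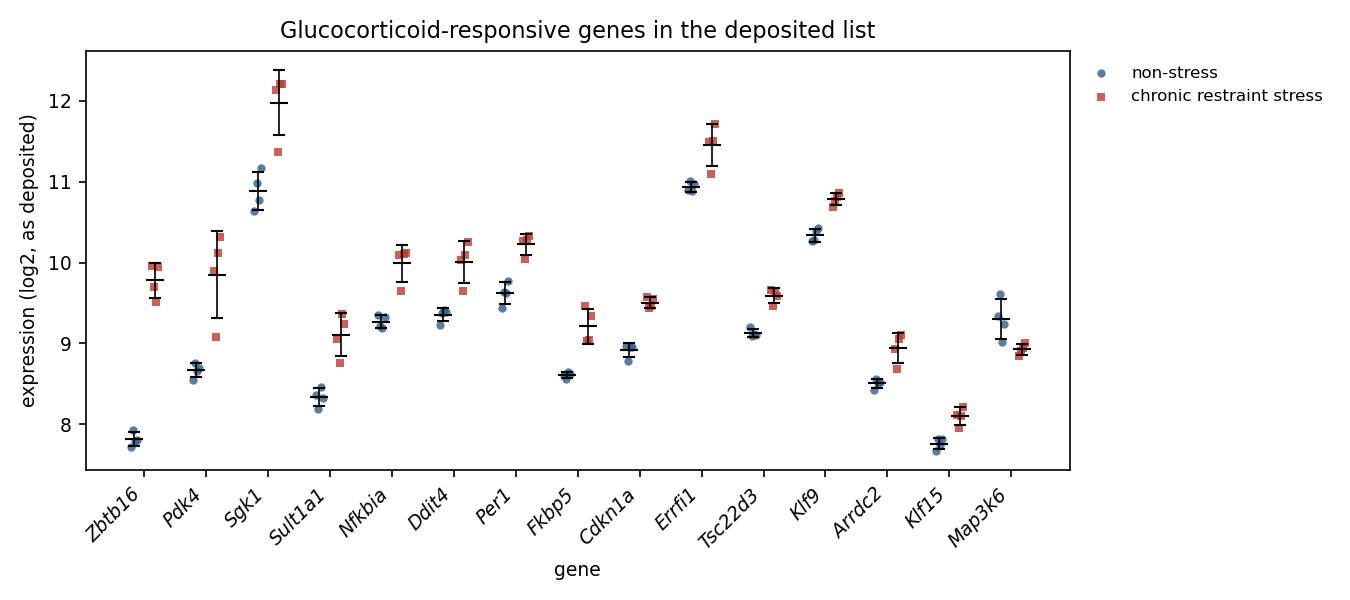
Expression (log2, vertical axis) of the 15 glucocorticoid responsive genes in the table for each rat, with circles for non-stress and squares for stressed rats and bars for the mean and SD of 4 rats. Of the 15 genes, 14 are higher in the stressed rats and Map3k6 is lower, and no gene has overlapping groups.

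Circadian clock genes were higher as well. The 5 members in the table, of 20 symbols in the list, were all higher: the period genes Per1 (0.61 ± 0.09), Per2 (0.48 ± 0.08) and Per3, the clock output transcription factor Dbp (0.31 ± 0.08), and Nr1d1, a nuclear receptor that represses Bmal1 (0.30 ± 0.08). Per3, chosen after its values were seen, was higher by 0.29 ± 0.07. All 5 passed over the whole table and all 5 adjusted over the list alone, which is not independent evidence because the table was chosen on these samples. The score difference was 0.40, and the direction differed from the rest of the table (Fisher's exact test, adjusted p = 0.0469). Per1 is also in the glucocorticoid list, and the direction test was not repeated without it.

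Markers of medial habenula neurons were lower. All 10 members in the table, of 20 symbols in the list, were lower in the stressed rats. Chrnb4, a nicotinic receptor subunit, was lower by a difference of -0.62 ± 0.12 (10.46 ± 0.04 against 11.09 ± 0.31). Slc18a3, the vesicular acetylcholine transporter, differed by -0.56 ± 0.11, Slc5a7, the choline transporter, by -0.54 ± 0.12, and Tac1, the substance P precursor, by -0.52 ± 0.09. The table counts were 10 of 10 past the threshold over all probe sets and 10 of 10 adjusted over the list alone, again in a table chosen on these samples. The score differed by -0.47, and the direction differed from the rest of the table (Fisher's exact test, adjusted p = 0.0100). The score had an SD of 0.19 among the non-stress rats and 0.02 among the stressed rats.

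Cholinergic synapse genes shared their 5 members in the table with the medial habenula list, namely Chrnb4, Slc18a3, Slc5a7, Chrnb3 (-0.48 ± 0.11) and Chrna3 (-0.35 ± 0.08), the last chosen after its values were seen. All 5 were lower and passed both over the table and adjusted over the list alone, in a table chosen on these samples. The score differed by -0.51. With 5 members, all of them lower, Fisher's exact test of direction could not pass (p = 0.0682, adjusted p = 0.150).

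**Figure D2:**
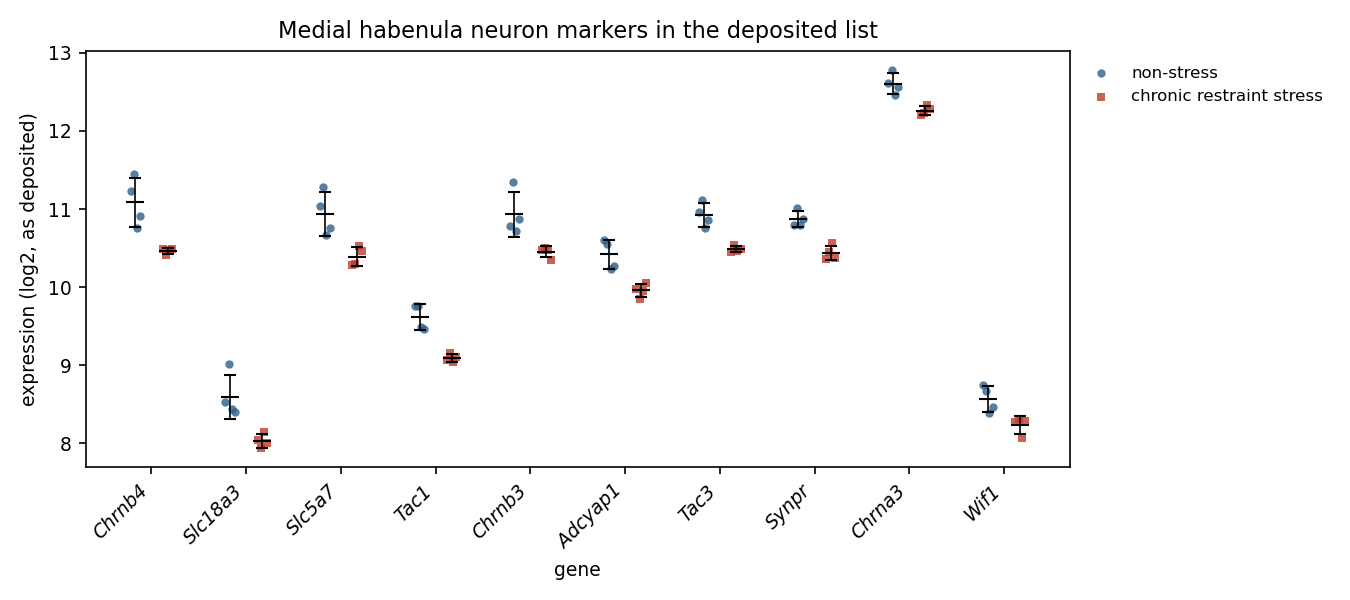
Expression (log2, vertical axis) of the 10 medial habenula neuron markers in the table for each rat, with circles for non-stress and squares for stressed rats and bars for the mean and SD of 4 rats. All 10 genes are lower in the stressed rats, with the wider spread among the non-stress rats.

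The 3 markers of hippocampal and dentate neurons in the table were all lower: the transcription factor Neurod1 (-0.48 ± 0.11), the vesicular glutamate transporter Slc17a7, which the medial habenula also expresses (-0.31 ± 0.08), and neurogranin, Nrgn (-0.28 ± 0.09). Fisher's exact test of direction could not pass for 3 members that were all lower (p = 0.257, adjusted p = 0.471). Their score differed by -0.36. Within groups it moved with the medial habenula score from rat to rat (residuals of 8 rats, Pearson's r 0.959, exact permutation within groups p = 0.00174; Spearman's rho 0.833, exact permutation p = 0.00347). Most of this variation lay among the non-stress rats, where the medial habenula score had an SD of 0.19, against 0.02 among stressed rats. Without non-stress rats 3 and 4, which lay farthest from the median, r was 0.627 (exact permutation p = 0.0833) and rho 0.886 (exact permutation p = 0.0417), so the size of r rests on those rats. Without non-stress rat 3 alone r was 0.841 (exact permutation p = 0.0903; rho 0.893, p = 0.0139) and without non-stress rat 5 alone 0.974 (exact permutation p = 0.0625; rho 0.893, p = 0.0417), so either rat ends the call on r. The link is not particular to hippocampal markers. The 200 lower probe sets outside the medial habenula list had a median residual r of 0.65 with that score, and 94 were over 0.7. Among monoamine genes, the serotonin receptors Htr3a (-0.41 ± 0.10), Htr4 (-0.34 ± 0.10) and Htr5b (-0.32 ± 0.09) and the decarboxylase Ddc (-0.31 ± 0.08) were lower. The remaining member, the adrenergic receptor Adra1d, chosen after its values were seen, was higher by 0.26 ± 0.08. The monoamine score differed by -0.22, without a direction distinguishable from the rest of the table (Fisher's exact test, adjusted p = 0.531). All members of both lists passed over the table and adjusted over the list alone, in a table chosen on these samples. After quantile normalization Nrgn no longer passed over the table, and Adra1d was not checked.

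Neuropeptides and their receptors went both ways, with 5 members higher and 7 lower of the 12 in the table. Oxytocin, Oxt, was higher by 0.59 ± 0.10 and vasoactive intestinal peptide, Vip, by 0.49 ± 0.08, while Tac1 and Adcyap1, the precursor of PACAP (-0.46 ± 0.10), were lower. The score difference was -0.08, or -0.17 without the dimmest 25% of probe sets and -0.28 as a median over genes, and the median member differed by -0.36 (Fisher's exact test of direction, adjusted p = 1). Voltage-gated and potassium channels had 4 members higher and 3 lower: the sodium channel Scn7a was higher by 0.64 ± 0.12, and Kcnh8 (-0.50 ± 0.10), Cacna2d2 (-0.42 ± 0.10) and Cacna1e (-0.40 ± 0.10) were lower. Their score difference was 0.05 (Fisher's exact test of direction, adjusted p = 0.861). Of 4 immediate early genes, Dusp1 (0.39 ± 0.11), Fos (0.27 ± 0.09) and Gadd45b (0.27 ± 0.08) were higher and Nr4a2 lower (-0.34 ± 0.11), with a score difference of 0.15 (Fisher's exact test of direction, adjusted p = 0.515). Among 5 cAMP signalling genes the phosphodiesterases Pde2a (-0.38 ± 0.10) and Pde1a (-0.35 ± 0.08) and the transcription factor Creb3l1 (-0.29 ± 0.10) were lower. Rapgef5, an exchange factor for Rap proteins, was higher by 0.35 ± 0.08, as was the adenylyl cyclase Adcy1, chosen after its values were seen (0.27 ± 0.08). The cAMP score difference was -0.08 (Fisher's exact test of direction, adjusted p = 1) and was 0.021 after quantile normalization. That scaling shifted the median difference of the table by 0.10 and turned the direction of 0 of the 5 members. Within groups, the 3 lower channel genes and the phosphodiesterases moved with the medial habenula score (residual r 0.79 to 0.97, computed after the values were seen). They are therefore not shown to be separate changes. Every member of these 4 lists passed on its own over the table and adjusted over the list alone, in a table chosen on these samples. After quantile normalization Cacna1e and Creb3l1 no longer passed over the table, and members outside the 63 genes named by the rule were not checked. That scaling was run on the chosen probe sets alone, so these losses may follow the scaling.

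Chemosensory receptor genes, which encode receptors of the olfactory, vomeronasal and taste systems, were a large group at low signal. Of the 21 in the table, 19 were higher and 2 lower in the stressed rats, at a mean level of 6.19 where the median probe set of an array lay at 8.60 or above. Or2t47 was higher by 0.44 ± 0.10, Or52n20 by 0.40 ± 0.12, Or1o11b by 0.39 ± 0.11 and Or4a77 by 0.38 ± 0.10. The 2 lower genes, named after their values were seen, were Or10d5jl (-0.37 ± 0.10) and Vom2r25 (-0.28 ± 0.09). The groups did not overlap in 12 of the 21. The score differed by 0.26 and the direction differed from the rest of the table (Fisher's exact test, adjusted p = 0.000129). All 21 passed over the table and adjusted over the list alone, in a table chosen on these samples. Among the other probe sets, 50 of the 90 in the same low range of signal were higher (55.6%), against 100 of the 268 brighter ones (37.3%).

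**Figure D3:**
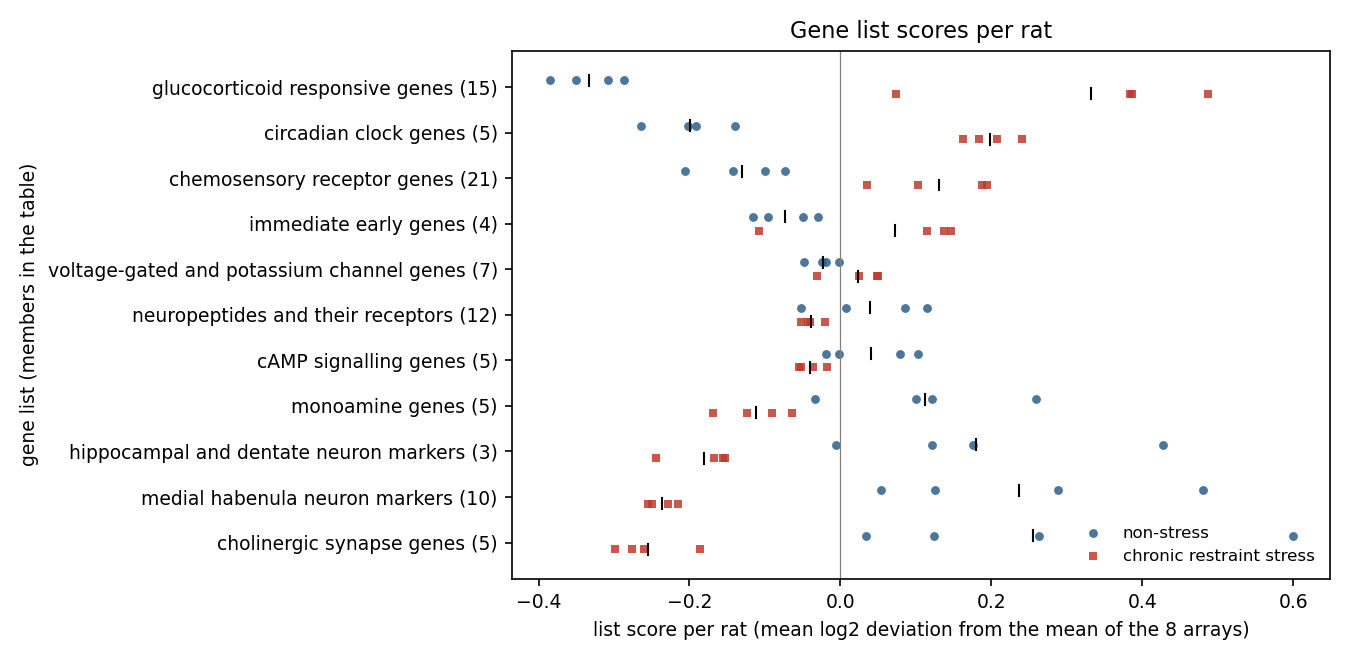
Score of each gene list per rat (horizontal axis, mean log2 deviation from the mean of the 8 arrays), for the 11 lists with at least 3 members in the table, with circles for non-stress rats, squares for stressed rats and a vertical tick for each group mean. The glucocorticoid, clock and chemosensory scores are higher in every stressed rat than in any non-stress rat, and the medial habenula, cholinergic, hippocampal and monoamine scores are lower in every stressed rat, in genes chosen for a difference between these arrays.

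Markers of other cell types were few. Of 2 lateral habenula markers, the secreted neuropeptide precursor Vgf was higher by 0.30 ± 0.08 and the orphan receptor Gpr151 lower (-0.42 ± 0.09). Of 2 microglial markers, Tmem119 was higher by 0.37 ± 0.10 and Gpr34 lower (-0.58 ± 0.09). The endothelial transporters Slco1a4 (-0.32 ± 0.08) and Slco1c1 (-0.29 ± 0.08) and the meningeal and GABA transporter gene Slc6a13 (-0.31 ± 0.10) were lower. The GABA receptor subunit Gabrd was higher by 0.27 ± 0.08, and the chaperone genes Hspb8 (-0.40 ± 0.09) and Dnajb3 (-0.28 ± 0.08) were lower. The glutamatergic list held Slc17a7 alone. These 7 lists had 1 or 2 members and were not tested as groups, although each member passed over the table and adjusted over its list alone, Slco1c1 no longer over the table after quantile normalization. The lists for thalamic neurons, choroid plexus, ependyma and subcommissural organ, pineal gland, oligodendrocytes, their precursors, astrocytes, blood cells, oxidative phosphorylation, ribosomal proteins and small non-coding RNAs had 0 members in the table, which does not show that such genes were unchanged.

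Outside the lists, Gpd1 was higher by 1.05 ± 0.10, and Hif3a, a hypoxia-inducible factor subunit, by 0.88 ± 0.09 (8.10 ± 0.14 against 7.21 ± 0.12). Apold1, an endothelial early response gene, was higher by 0.87 ± 0.14, the ceramidase Acer2 by 0.84 ± 0.12, the secreted phospholipase Pla2g3 by 0.78 ± 0.09, the thiamine transporter Slc19a3 by 0.76 ± 0.13 and the focal adhesion gene Lims2 by 0.68 ± 0.08. Among the lower genes, Cd180, a Toll-like receptor relative of immune cells, differed by -0.73 ± 0.10 (7.94 ± 0.09 against 8.67 ± 0.20), the cytochrome P450 Cyp2j4 by -0.71 ± 0.14 and the membrane metalloproteinase Mmp14 by -0.67 ± 0.09. The vasoconstrictor peptide gene Edn1 differed by -0.58 ± 0.14 and the synaptotagmin Syt6 by -0.57 ± 0.11.

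**Figure D4:**
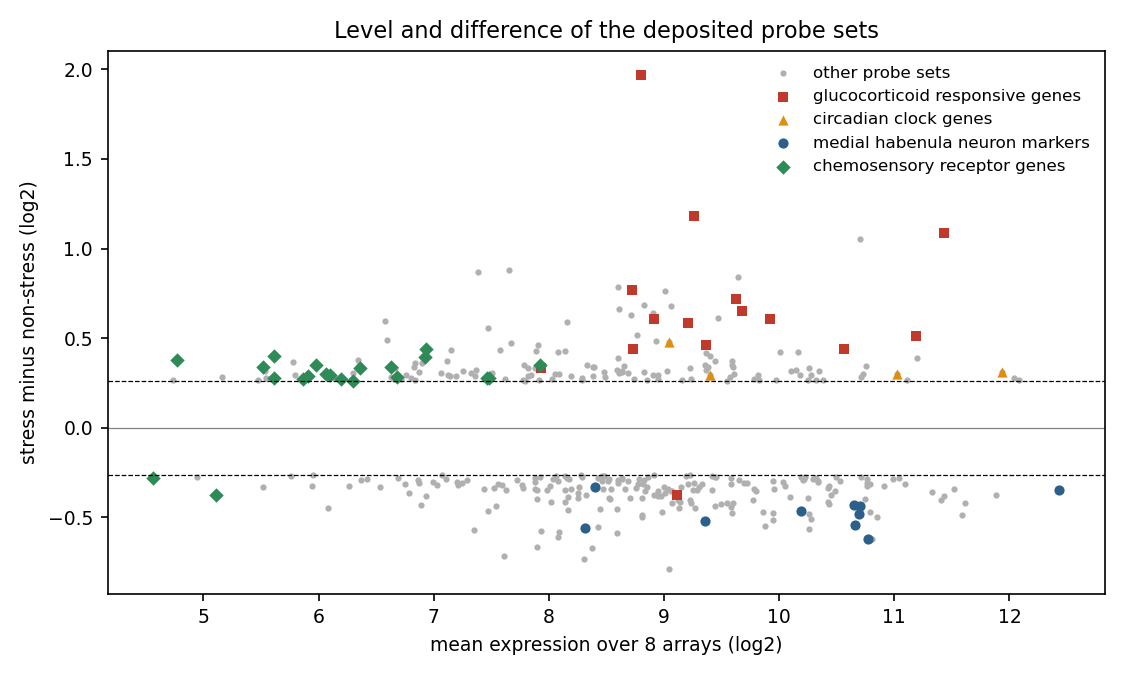
Difference between the groups (log2, stress minus non-stress, vertical axis) against mean expression over 8 arrays (log2, horizontal axis) for the 379 probe sets, with 4 gene lists marked and dashed lines at a fold of 1.2 in either direction. No probe set lies between the dashed lines, and the chemosensory genes gather at low expression.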

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

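Recomputing the clock test without each rat was chosen only after its result over all 8 rats was seen; the other tests of this part were not. Of 148 group values tested for a single rat lying apart from the other 3, 9 were found, and chance gives about 1 in 20.

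Stressed rat 8 accounts for 4 of the 9. Its level of the kinase gene Sgk1 was 11.37, against 12.13 to 12.20 in the other stressed rats. Its level of Nfkbia was 9.64, against 10.10 to 10.11. Its immediate early gene score was -0.11, against 0.12 to 0.15. Its level of Ddc was 9.27, against 9.04 to 9.06. In stressed rat 7, the hippocampal and dentate score was -0.24, against -0.17 to -0.15, and the calcium channel subunit Cacna2d2 was at 10.29, against 10.18 to 10.20. Gpr149 was at 8.82 in stressed rat 12, against 8.58 to 8.60. Nr1d1 was at 10.99 in non-stress rat 5, against 10.82 to 10.84, and Dnajb3 was at 7.94 in non-stress rat 1, against 8.03 to 8.05.

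In stressed rat 8 the glucocorticoid score was 0.07 (0.38 to 0.49 in the other stressed rats), whereas its clock score was 0.21 (0.16 to 0.24). A candidate explanation for the joint rise of both lists is 1 response that the clock genes share with the glucocorticoid responsive genes in each rat, which would make them vary together within groups. The mean correlation of within-group residuals between the 4 clock genes outside the glucocorticoid list and that list was -0.0925, at percentile 1.29 of random lists of higher probe sets, the opposite of that prediction. Without stressed rat 8 it was 0.265, at percentile 98.25, so this single rat decides the outcome and a shared response cannot be told apart from separate ones. A difference between the groups in the hour of dissection stays open and was not tested.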

How the results depend on the processing

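The number-of-tests adjustment and the direction test were chosen only after the data were seen. Assuming 5000, 10000, 20000 or 30000 probe sets tested, 12, 2, 1 and 1 of the 379 passed, because the adjustment grows with the number assumed. The equal-variance test, both other limma fits, median-centring and the looser thresholds called all 379, and leaving out 1 rat 378 to 379, which shows no stability in a table chosen for small p-values; quantile normalization, which shifted the median difference by 0.10, called 336. Without the dimmest 25%, 109 probe sets were higher, and no chemosensory score was computed. Fewer were tested, and dim probe sets outside the chemosensory list were higher more often than brighter ones (55.6% against 37.3%). The permutation calls of list scores are void because the members were chosen on these arrays, so only the sizes of score differences are compared. The cAMP score difference of -0.08 turned to 0.021 under quantile normalization, which shifted the median difference of the table by 0.10. None of its 5 members turned in direction, so the sign of this small score follows the scaling. The neuropeptide difference grew without the dimmest 25% (-0.17), a filter that left out the higher members Vip (mean level 6.60, difference 0.49) and Nts (difference 0.27). As a median over genes it was -0.28, with 7 of the 12 members lower. Other causes were not tested. Without the gene shared by the clock and glucocorticoid lists, added after the data were seen, the differences were 0.35 for clock and 0.67 for glucocorticoid. Without the cholinergic genes, also added, that of medial habenula was -0.44, with members shared with the neuropeptide list kept. The direction test was not repeated for these shortened lists, so the clock and medial habenula calls by direction may rest on shared genes. By the direction test, the hippocampal (-0.36), cholinergic (-0.51) and monoamine (-0.22) lists did not pass, with few members each. With so few members the test could not pass even where all were lower, so it does not show a lack of direction. Without 1 rat the score differences ranged from -0.54 to -0.39 for medial habenula, -0.58 to -0.40 cholinergic, -0.42 to -0.28 hippocampal, -0.27 to -0.17 monoamine, 0.61 to 0.75 glucocorticoid, 0.38 to 0.42 clock, 0.24 to 0.29 chemosensory, -0.10 to -0.060 cAMP and -0.11 to -0.053 neuropeptides. Of the 63 genes named by the rule, Nrgn, Slco1c1, Cacna1e and Creb3l1 were no longer past limma's threshold after quantile normalization. Each is a lower gene, and that scaling, run on the chosen probe sets alone, shifted the median difference upward by 0.10. These losses may therefore follow the scaling. Other genes were not checked singly. Signal over background is not given in the sources used here, which limits the dim genes most.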

Other observations

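The level-matched comparison of chemosensory genes, the recomputation of the medial habenula test without each rat and the correlations with the medial habenula score were chosen only after results were seen.

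Further genes of the table are described here, all chosen after their values were seen. Several receptors of the neuropeptide list were lower in the stressed rats: the somatostatin receptors Sstr4 (-0.42 ± 0.10) and Sstr2 (-0.33 ± 0.10), the neurotensin receptor Ntsr1 (-0.38 ± 0.09) and the substance P receptor Tacr1 (-0.39 ± 0.11). The neuropeptide Y receptor Npy1r was higher by 0.37 ± 0.09. The substance P receptor was thus lower together with Tac1, which encodes its ligand, whereas the neurotensin gene Nts was higher by 0.27 ± 0.09 where its receptor was lower. Tac3, the neurokinin B precursor, was lower (-0.44 ± 0.09).

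The transcriptional repressor Bcl6 was 1.60-fold higher (0.68 ± 0.10), and the calcium-binding protein gene Pvalb was 1.55-fold higher (0.63 ± 0.14) with overlapping groups. The interferon-inducible genes Mx1 (-0.32 ± 0.10), Ifi44l (-0.29 ± 0.08) and Gbp5 (-0.29 ± 0.08) were lower without overlap, and Psmb9, an immunoproteasome subunit, was lower (-0.58 ± 0.13) with overlap. The vascular surface proteins Cd34 (-0.35 ± 0.09) and Cd93 (-0.30 ± 0.08) were lower, while the flow-responsive transcription factor Klf2 was higher by 0.29 ± 0.08 and the glucose transporter gene Slc2a1 by 0.27 ± 0.08. All of these passed limma's threshold in a table chosen on these samples, and no list of such genes was tested.

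A smaller share of medial habenula tissue in the stressed dissections would make the 10 lower medial habenula markers vary together from rat to rat within groups, and their mean pairwise residual correlation was 0.671, at percentile 99.3 of random lists of lower probe sets. Without non-stress rat 3 it was 0.385, at percentile 90.25, so that rat decides whether the correlation stands out. The tissue share thus cannot be told apart from lower expression per cell after stress, which stays open and was not tested. The medial habenula score had an SD of 0.02 among the stressed rats and 0.19 among the non-stress rats. This correlation and those below therefore rest mostly on the 4 non-stress rats. Of the other 200 lower probe sets, 94 had a residual correlation over 0.7 with the medial habenula score (73 to 105 without 1 rat, the lowest without non-stress rat 3), where reordering the rats within groups gave a median of 4 and a 95th percentile of 85 (exact permutation p = 0.0295, not repeated without each rat). In reverse, 21 of the 169 higher probe sets were under -0.7 (22 to 32 without 1 rat, the highest without stressed rat 7), which did not exceed what reordering gave (median 7, exact permutation p = 0.155). Genes described above in separate groups were among those over 0.7: Cacna1e (0.97), Pde2a (0.96), Cacna2d2 (0.94), Kcnh8 (0.93), Ntsr1 (0.91), Htr3a, Sstr4, Htr4, Sstr2, Pde1a and Htr5b (0.76). Scn7a (-0.95), Adcy1 (-0.87) and Npy1r (-0.78) were under -0.7. Tacr1 (0.59), Creb3l1 (0.54) and Ddc (0.37) did not reach 0.7. The genes past 0.7 in either direction are therefore not shown to have changed apart from the medial habenula markers. Of neighbouring markers, the lateral habenula genes went apart (Gpr151 -0.42, Vgf 0.30). Within groups both followed the medial habenula score, in opposite directions (residual r 0.892 for Gpr151 and -0.739 for Vgf). The 3 hippocampal and dentate genes were lower, with a score that followed the medial habenula score (r 0.959). That r was 0.841 without non-stress rat 3 (exact permutation p = 0.0903) and 0.974 without non-stress rat 5 (exact permutation p = 0.0625). These are few genes, the medial habenula also expresses Slc17a7, and the tissue share stays open.

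The chemosensory genes, 19 of 21 higher, were at low signal for this table, with 20 of the 21 at a mean level up to 7.88. Signal near the floor raised in the stressed arrays is a candidate explanation, and 55.6% of the other dim probe sets were higher against 37.3% of the rest (Fisher's exact test, p = 0.00299). This level trend alone gives fewer: lists of other probe sets matched on mean level had a median of 12 higher and a 95th percentile of 15, and 19 lay at percentile 99.94. Probes shared between related receptor genes, and a real increase of receptor transcripts after stress, stay open and were not tested.

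Among the 35 splits of the 8 arrays into 4 and 4, only the real one (1 of 35) called all 379 probe sets, and the highest of the others called 15. Because the table was chosen on the real split, this comparison is void and says nothing about chance.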
